A study of Drosophila melanogaster with 4 samples.

How the data were processed

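The series profiled the binding of Deformed (Dfd), a Hox transcription factor of the embryonic head, by chromatin immunoprecipitation and sequencing (ChIP-seq) in Drosophila melanogaster. Per the labels, the flies carried a genomic Dfd transgene whose stop codon was replaced by green fluorescent protein (GFP), and the immunoprecipitation used a rabbit polyclonal antibody against GFP. The 4 libraries were 2 GFP ChIP libraries and 2 input libraries of embryos labelled 0 to 8 h. The collection protocol in the labels describes another window, 8 to 16 h, and another fly stock; the stage is given here as labelled, and the conflict was left open.

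The authors deposited 1 peak list for the whole series, and it was the only processed file used here. Per the submitters' processing notes, CASAVA 1.7.0.2, CASAVA 1.7.0.3, BWA and MACS2 were used with the build BDGP5; the notes give no roles, settings or order. Per the file headers, coordinates are on FlyBase release 5, and each entry names MACS as its source. The list holds a start, an end and a score per peak and ties no value to a library. Whether replicates were pooled before calling, the threshold applied, and the treatment of reads with several alignments are not given in the sources used here. The read depth of each library is likewise unknown, so no interval that needs depth was computed.

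The headers name no unit for the score, which was settled from the values. For each background rate from 20 to 400 in steps of 0.01, the scores were compared with −log10 of the upper tail probability of a Poisson distribution with that mean, equal to 2 decimals. A rate of 80.06 matched 3875 of the 7683 scores (50.4%), against a median of 240 for rates within 20 of it and 1988 for the best other rate in the range. The deposited scores were therefore read as unadjusted −log10 p of the peak caller, with 80.06 as the background rate shared by the most peaks; the unit and the rate are inferred and not stated by the authors. For matched peaks, this gives the pileup of fragments at the most enriched point and its ratio to the background rate. Scores are the authors' values, and they were compared only among peaks of this list.

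Peaks were grouped by sequence into the 6 chromosome arms (2L, 2R, 3L, 3R, X and 4), 6 scaffolds of placed heterochromatin (Het), the unplaced sequence U, the additional unplaced sequence Uextra, and the mitochondrial genome. No peaks overlapped. Shares of peaks have exact (Clopper-Pearson) 95% binomial intervals, densities have exact Poisson intervals, and medians have bootstrap intervals; all cover counting error within this list only. Peaks are not independent replicates, so p-values describe this list and not the spread between embryo collections.

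Clustering was tested by placing the peaks of each arm at random over the span from its first to its last peak, 10000 times; the statistic was the share of peaks with another midpoint within 5000 bp (one-sided). For merged peaks, the statistic was the share of regions with another within 5000 bp edge to edge, and as many regions of the same widths were placed at random with every gap over the merging distance, over the span or within windows of 500 kb. Runs were chains of at least 5 arm peaks with gaps of at most 2000 bp, and isolated peaks were arm peaks outside runs with no other midpoint within 5000 bp. Enrichment at the centromere-proximal ends was tested with 10000 circular shifts within each of the 5 large arms (one-sided). These ends were the last 1 Mb of the spans of 2L, 3L and X and the first 1 Mb for 2R and 3R. Medians of scores were compared by two-sided permutation tests with 100000 resamples, with Benjamini-Hochberg adjustment over the 3 such comparisons; the other p-values are unadjusted. The widths of arm and Uextra peaks were compared likewise with 10000 resamples. The relation of score and width was tested by permuting Spearman's rho with 100000 resamples. Strong peaks were the top 10% of the list by score (52.26 or more, 770 peaks with ties). The smallest p that 10000 placements and 100000 resamples can give is 0.0001 and 1e-05. The tests were tested on simulated data. Of 40 lists of 2625 peaks placed at random, the clustering test called 1, and it called 40 of 40 lists in which peaks had been given partners. The test of merged peaks called 1 of 40 random lists, both over the span and within windows, and 40 of 40 lists in which regions had partners. It also called 1 of 40 lists of regions split into pieces, over the span and within windows. The gaps between pieces were under 2000 bp, so that merging joined them again. Lists split at wider gaps were not simulated. The proximal test called 4 of 40 lists with no preference for an end (nominal rate 5%). Peaks of those lists were grouped only in pairs, less than in the real list. Its rate of false calls at the real grouping is therefore unknown. The test of score and width called 3 of 40 unrelated sets of 500 peaks, and the test of medians 1 of 40. The background rate was recovered in 5 of 5 simulated lists. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

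The peaks to name, the 20 with the highest score (ties by position), were fixed before the data were examined, as were the clustering test and the test of score and width. The runs, the strong neighbourhoods, the proximal test, the comparisons of medians, the Fisher test and the reading of the score were chosen after seeing the data. The planned tests of genomic features, start sites, gene lists and motifs, and of scores by gene list, were not run: the gene table used here is on release 6, no release 5 sequence or annotation was used, and coordinates were not converted between builds. Alternatives tried were stricter score limits, merging of nearby peaks, other distances, runs defined otherwise, and single arms left out. The binomial test of peaks per arm needed release 5 arm lengths and was replaced by a description over spans, as planned for that case. Regions are therefore named by release 5 coordinates, counted from 1, and no gene is assigned to a peak.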

Results

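Dfd specifies the mandibular and maxillary segments of the Drosophila embryo, and the series asked where the GFP-tagged protein is bound in embryos labelled 0 to 8 h, with 2 GFP ChIP and 2 input libraries. The deposited result was 1 list of 7683 peaks covering 3379 kb of the release 5 assembly. Peaks had a median width of 341 bp (quartiles 261 to 484 bp, range 201 to 19741 bp). Their scores, −log10 p of enrichment over background, had a median of 13.7 and ran from 5.77 to 678.18. Because the list carries no values per library, the replicates could not be compared, and the errors below describe variation among peaks or counting error.

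A fold over background could be inferred for part of the list. For the 3875 peaks whose score matched the Poisson tail at the background rate of 80.06, the inferred pileup at the most enriched point was a median of 1.94-fold over that rate (quartiles 1.81 to 2.07). The range was 1.57-fold to 7.77-fold. Arm peaks of this kind reached a median of 2.00-fold, with an upper quartile of 2.37-fold. Those on Uextra had a median of 1.92-fold and an upper quartile of 2.02-fold. The highest matched ratio, 7.77-fold, was shared by the peak on 2R at bases 6315705 to 6316491 and the peak on 3L at bases 18081056 to 18081701. No ratio was derived for peaks whose score did not match, among them 17 of the 20 with the highest score. A match needed equality to 2 decimals at a rate searched in steps of 0.01, and the same error in the rate shifts high scores more. Unmatched peaks can therefore share the rate. The medians, quartiles and maximum above hold for matched peaks alone and can leave out higher ratios.

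**Figure D1:**
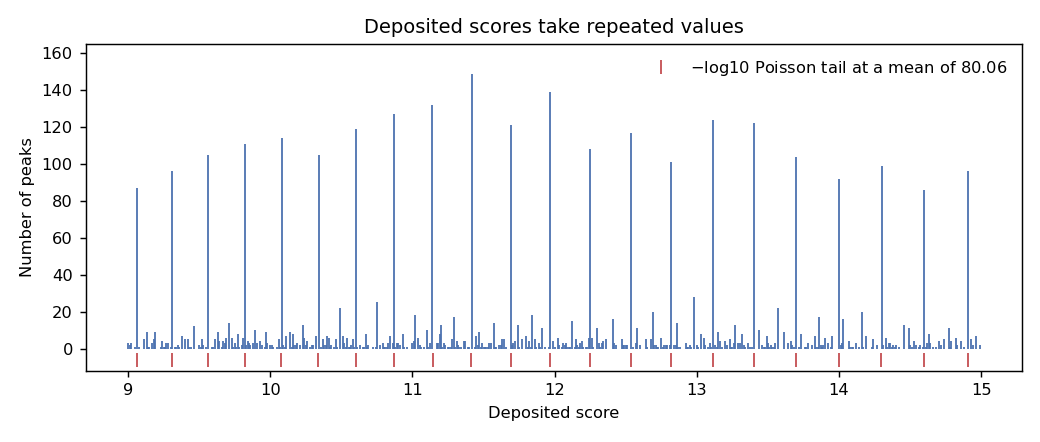
Number of peaks (vertical axis) at each deposited score between 9 and 15 (horizontal axis, −log10 p, 2 decimals). Red ticks mark −log10 of the Poisson tail probability at a mean of 80.06; the tall lines stand at the ticks, and 3875 of all 7683 scores match such values.

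The first comparison was of parts of the genome. Uextra, the additional unplaced sequence of release 5, held 4114 peaks, or 53.5% of the list (95% interval 52.4 to 54.7%). The 6 chromosome arms held 2625 peaks (34.2%, interval 33.1 to 35.2%), the Het scaffolds 369 (4.80%, interval 4.34 to 5.30%) and the unplaced sequence U 571 (7.43%, interval 6.86 to 8.04%). The strong peaks were distributed differently. Of the 770 peaks in the top 10% by score, 395 lay on the arms (51.3%, interval 47.7 to 54.9%) and 332 on Uextra (43.1%, interval 39.6 to 46.7%). The median score was 14.31 on the arms (interval 14.03 to 14.7) and 13.49 on Uextra (interval 13.4 to 13.7), a difference of 0.82 (two-sided permutation test, p = 2e-05, adjusted p = 2e-05). The medians lay close together, and the classes parted in the upper part of the range, where the upper quartile was 28.32 on the arms and 17.62 on Uextra. Among the top 50% of all peaks by score, the medians were 24.87 on the arms and 17.78 on Uextra. Arm peaks were also wider, with a median of 399 bp against 323 bp (permutation p = 0.0001, the smallest that the resamples can give). Across all peaks, higher scores went with greater width (Spearman's rho = 0.56, permutation p = 1e-05, the smallest possible, across peaks, which are not independent replicates). Both values are set by the peak caller, so this relation says little about binding.

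**Figure D2:**
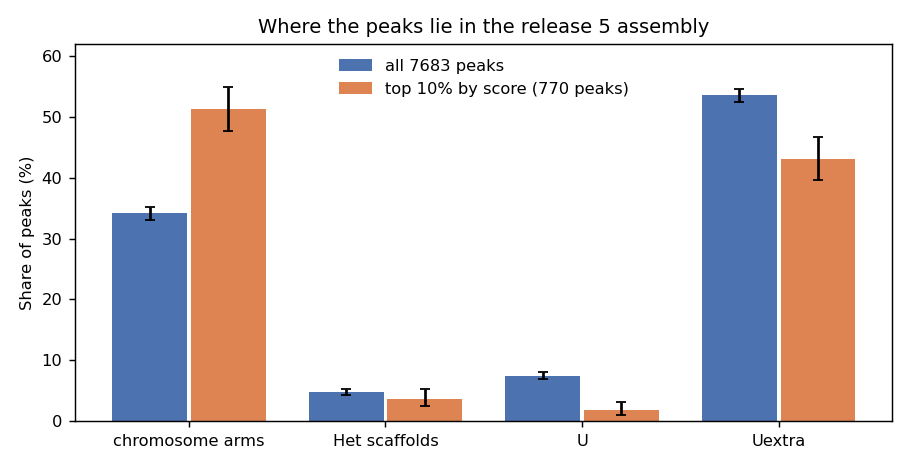
Share of peaks in percent (vertical axis) on the chromosome arms, Het scaffolds, U and Uextra, for all 7683 peaks (blue) and for the 770 peaks in the top 10% by score (orange); bars carry exact 95% binomial intervals. Uextra holds 53.5% of all peaks and 43.1% of the strong ones, and the arms hold 34.2% and 51.3%; 4 mitochondrial peaks are not drawn.

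The strongest peaks lay mainly on the arms of the major autosomes. Of the 20 peaks with the highest score, 6 were on 3R, 5 on 2L, 4 on 2R and 3 on 3L, and the other two were on the heterochromatic scaffolds 3LHet and 2RHet. The last of the 20, on 2L, was tied at 310.44 with a peak on 2R at bases 6310745 to 6311809 and was taken by its position. None of these 20 was on X, on chromosome 4 or on Uextra. The highest score, 678.18, belonged to a 632-bp peak on 2R at bases 15993781 to 15994412. It was followed by a 907-bp peak on 3L at bases 6117918 to 6118824, with a score of 530.34. A 1190-bp peak on 3R at bases 2733453 to 2734642 scored 527.28. On the same arm, a 978-bp peak at bases 8537872 to 8538849 scored 501.12. The fifth, on 2L at bases 5000827 to 5004976, was much wider at 4150 bp and scored 498.66. The heterochromatic pair were the peak on 3LHet at bases 1396264 to 1397533, with a score of 411.64, and that on 2RHet at bases 471589 to 472690, with a score of 317.52. The other 13 of the 20 scored between 310.44 and 407.83 and were 511 to 1251 bp wide. They lay on 3R from bases 8889462, 11798486, 17405291 and 18222844, on 2L from bases 8477751, 12520181, 16049527 and 19791018, on 2R from bases 1180733, 6315705 and 20744393, and on 3L from bases 14667015 and 18081056.

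Among the arms, chromosome 4, the small and largely heterochromatic autosome, had the most peaks for its size. It held 85 peaks over a span of 1.26 Mb from first to last peak, or 67.4 per Mb (95% Poisson interval 53.9 to 83.4). The large arms ranged from 18.7 per Mb on 3R (interval 17.2 to 20.4) to 23.6 per Mb on 2R (interval 21.5 to 25.7). Densities were 19.9 per Mb on 2L, 22.7 on 3L and 22.6 on X. Spans stood in for arm lengths here, so densities were described and not tested. The peaks of chromosome 4 were also stronger. Their median score was 29.98 (interval 23.75 to 45.43) against 14.3 over the large arms (interval 13.95 to 14.6; two-sided permutation test, p = 1e-05, the smallest possible, adjusted p = 1.5e-05). On chromosome 4, 32 of 85 peaks (37.6%) were among the top 10% of the list, against 363 of 2540 (14.3%) on the large arms (Fisher's exact test, two-sided, p = 1.67e-07). Without peaks in runs, which lay almost wholly on the large arms, the shares were 32 of 80 (40%) and 345 of 1578 (21.9%; Fisher's exact test, two-sided, p = 0.000509).

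Peaks were denser at the centromere-proximal ends of the large arms. These are ends of the spans of arm peaks, which leave out the Het scaffolds. The 1 Mb nearest the centromere on the spans of the 5 large arms held 229 peaks, 2.13 times the mean of 107 under circular shifts (one-sided permutation p = 0.0001, the smallest possible). The density in that interval was 54 per Mb on 2R against 22.0 over the rest of the arm. It was 52 against 21.5 on 3L, 48 against 18.6 on 2L, 39 against 18.0 on 3R, and 36 against 22.0 on X. The proximal density was higher on 5 of 5 arms.

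**Figure D3:**
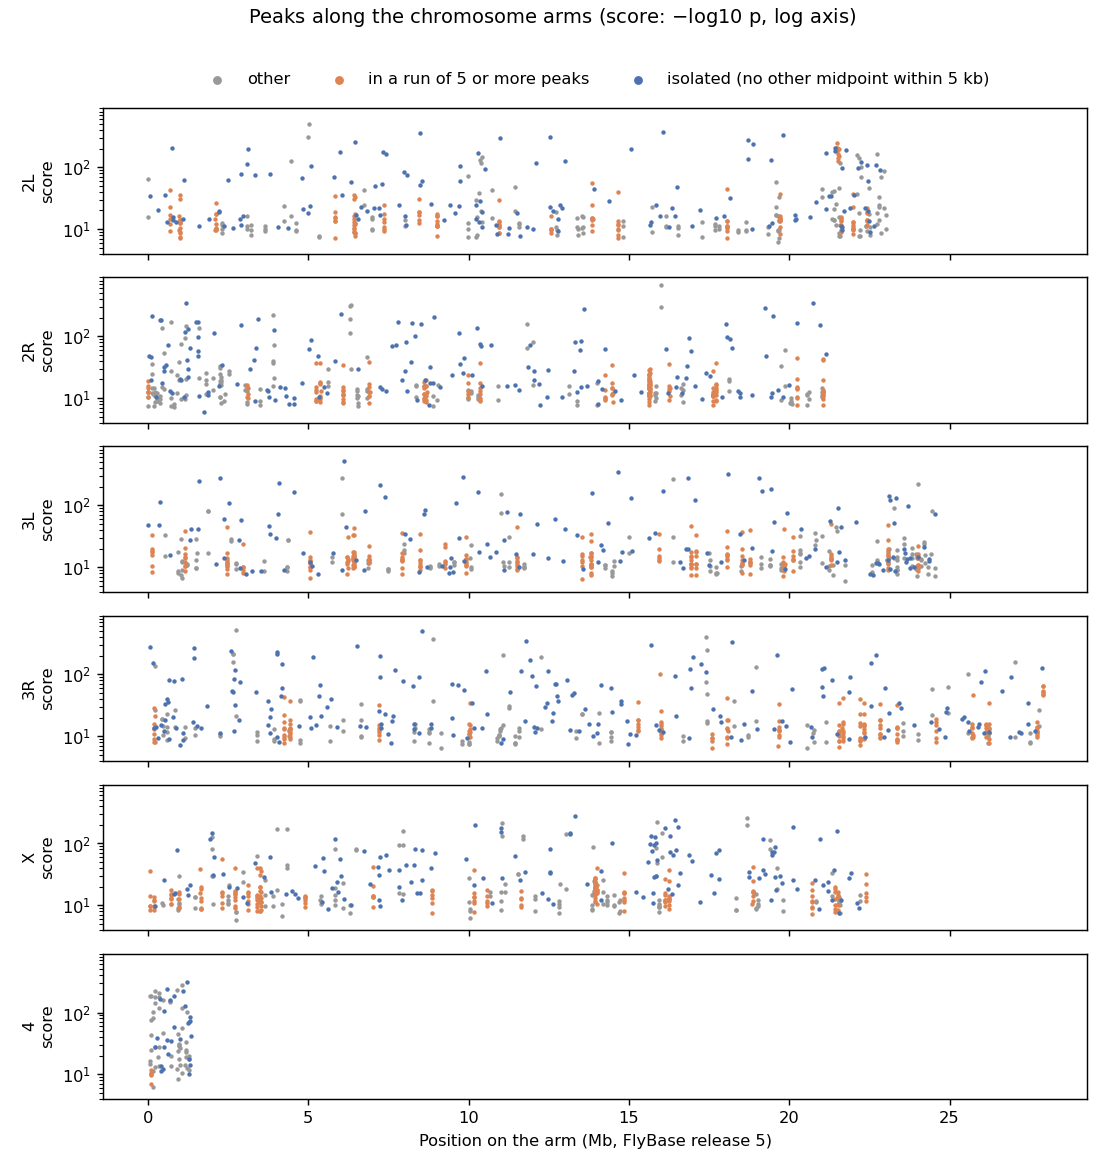
Score of each arm peak (vertical axis, −log10 p, log axis) against its position (horizontal axis, Mb, release 5), one panel per arm. Orange points are peaks in runs of 5 or more, blue points are isolated peaks and grey points are the rest; the 831 isolated peaks have a median score of 24.87 and the 967 run peaks one of 13.11.

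The next question was whether peaks stand alone or in groups. Of the 2625 arm peaks, 1786 (68.0%) had another peak midpoint within 5000 bp. Random placement gave a mean of 20.3% and at most 24.6% (one-sided permutation p = 0.0001, the smallest possible). The share was 60.3% or more on each of the 6 arms taken alone; on chromosome 4, where peaks are dense, it was 69.4% against 48.6% at random. With arm peaks within 2000 bp merged, 18.9% of the 1378 regions had another within 5000 bp edge to edge, against a mean of 7.57% and at most 11.3% at random (one-sided permutation p = 0.0001, the smallest possible). With merging within 1000 bp, the share was 40.6% against 11.2%. Strong peaks were rarer in runs than among isolated peaks. The list held 114 runs, with 967 peaks (36.8% of arm peaks, interval 35.0 to 38.7%), and 831 isolated peaks (31.7%, interval 29.9 to 33.5%). Run peaks had a median score of 13.11 (interval 12.79 to 13.4). Isolated peaks had a median of 24.87 (interval 22.28 to 27.97), so that run peaks were lower by a difference of −11.76 (two-sided permutation p = 1e-05, the smallest possible, adjusted p = 1.5e-05). The test shuffled single peaks, although the 967 run peaks belong to 114 runs, so its p can be too small. Most runs held a peak above 24.87, so the difference holds for single peaks and not for the highest peak of each run. Runs were not tested as units. Isolation was judged by midpoints, so that 17 isolated peaks had another peak within 5000 bp edge to edge, among them 2 wide adjoining peaks on 2L from bases 21416353 and 21429026; the median was also 24.87 for the other 814. Of the isolated peaks, 270 (32.5%) were among the top 10% of the list, against 18 run peaks (1.86%), and 12 of those 18 were in a single block on 2L. The rest of the 395 strong arm peaks lay among the 827 arm peaks that were neither in runs nor isolated. Widths were similar, with medians of 424 bp in runs and 404 bp for isolated peaks.

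The runs were of like length. Of the 114 runs, 76 were 7 to 10 kb long, and 52 of these were between 8 and 9 kb. Only 10 were longer than 10 kb, and 28 were shorter than 7 kb. The 76 runs were spread over 5 arms, with 20 on 3L, 18 on 3R, 13 on 2L, 13 on X and 12 on 2R. Their 628 peaks had a median score of 13.02, and 1 of them was among the top 10% of the list. The run with most peaks was far longer. It held 38 peaks over 36.8 kb of 2R, bases 15617041 to 15653847, with a median score of 15.05 and a highest score of 29.08. The next held 24 peaks over 26.2 kb of 3L, bases 6398884 to 6425105, with a highest score of 43.62.

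**Figure D4:**
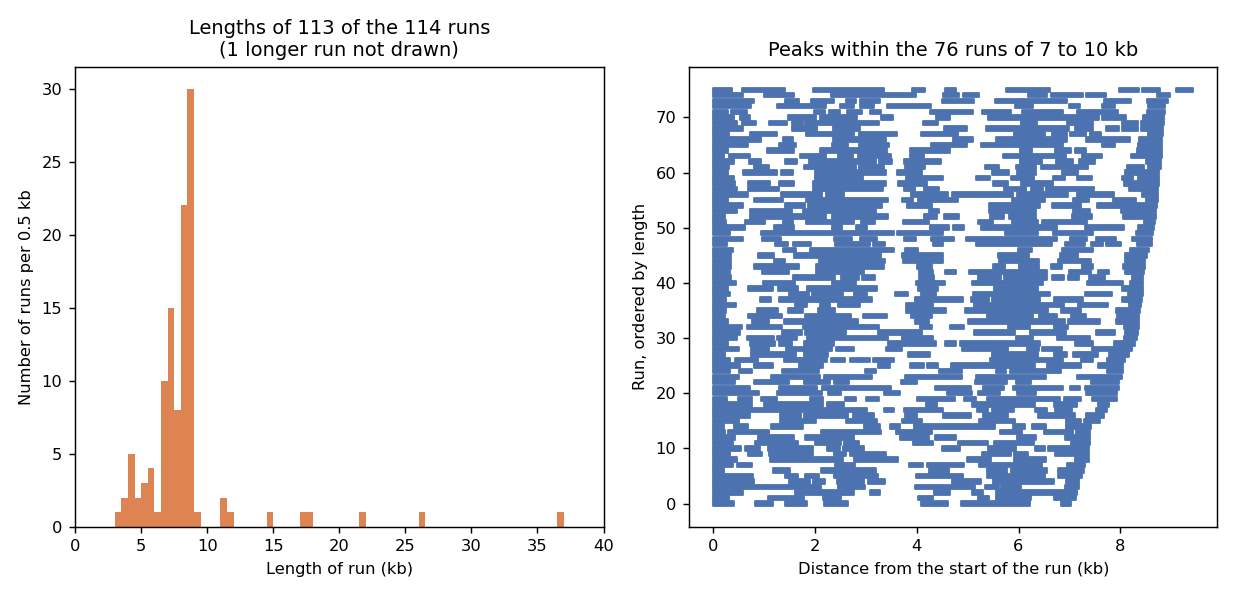
Left, number of runs per 0.5 kb of length (horizontal axis, kb) for 113 of the 114 runs; the longest, 93.5 kb, is not drawn. Right, each of the 76 runs of 7 to 10 kb as a row, with its peaks drawn to scale from the start of the run (horizontal axis, kb); 52 of the runs end between 8 and 9 kb.

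Strong peaks were also linked into neighbourhoods, which were described and not compared with random placement. Linking the 395 strong arm peaks across gaps of at most 30000 bp gave 10 neighbourhoods with at least 4 strong peaks. The largest, on 2L at bases 21416353 to 21573521, held 15 strong peaks, and its peaks covered 75.3% of 157 kb. Its core, bases 21450215 to 21543676, was a single run of 12 peaks covering 94.7% of 93.5 kb, with scores of 128.46 to 250.81 and widths of up to 17987 bp. In the other 9 neighbourhoods, peaks covered between 5.64 and 28.2% of the bases. On 3R, bases 2593962 to 2648422, 6 peaks covered 6.28% of 54.5 kb, each of them strong, with a highest score of 242.99. On 2R, bases 6305411 to 6316491, 4 strong peaks in 11.1 kb reached 321.08. On 3R, bases 17405291 to 17445842, 4 strong peaks among 7 reached 407.83. On X, 4 strong peaks in 29.3 kb at bases 11002670 to 11032007 reached 213.11, and 4 in 51.1 kb at bases 15784018 to 15835102 reached 127.67. Chromosome 4 had neighbourhoods at bases 1047580 to 1082338 and 1202160 to 1264655, with highest scores of 281.69 and 306.92. The others were on 2R at bases 1540201 to 1585452, reaching 171.43, and on 3R at bases 27877632 to 27903688, reaching 126.32. The latter took 3 of its 4 strong peaks from a run at bases 27898916 to 27904643.

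**Figure D5:**
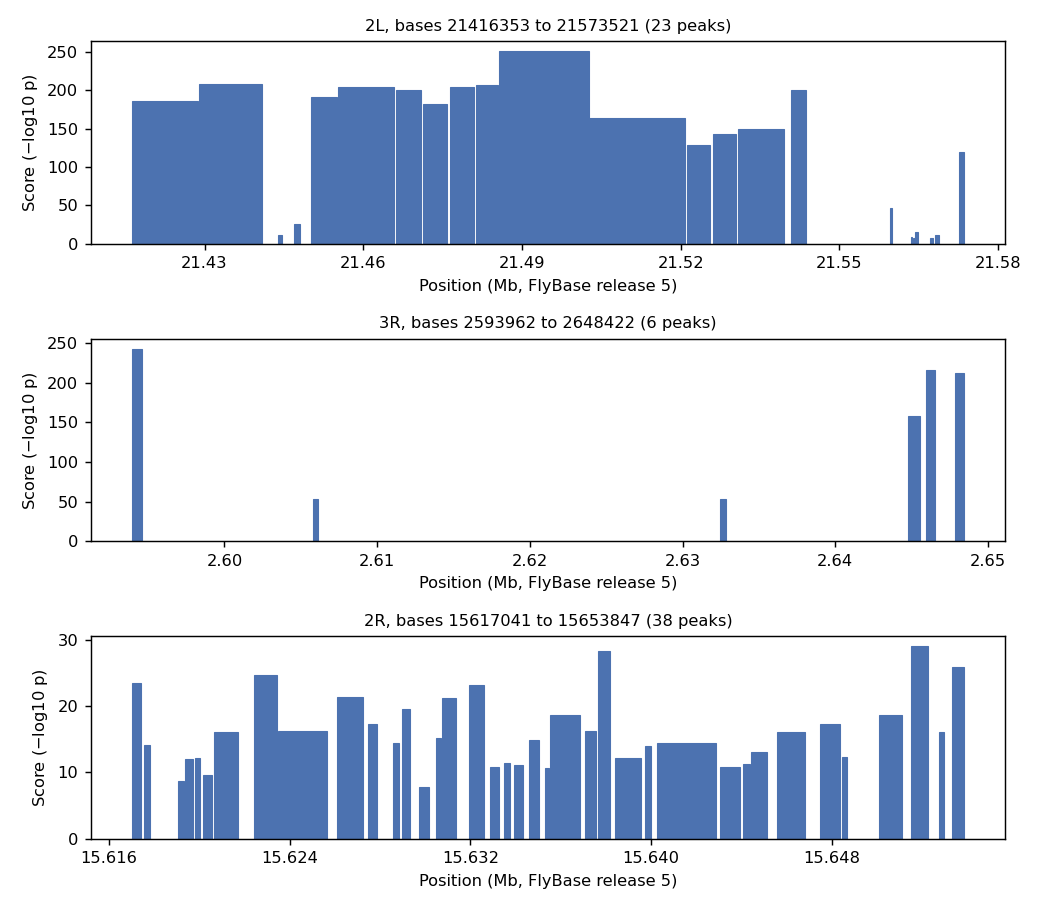
Score of each peak (vertical axis, −log10 p, from 0) drawn at its position and width (horizontal axis, Mb, release 5) in 3 regions. The top panel is the neighbourhood on 2L with wide adjoining peaks of up to 250.81, the middle panel the 6 separate strong peaks on 3R between bases 2593962 and 2648422, and the bottom panel the run of 38 weak peaks on 2R, none above 29.08.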

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

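The mitochondrial genome, which was set against no other part of the genome, held 4 peaks. Their scores were 27.05, 17.95, 32.95 and 103.89, and the highest belonged to a 2520-bp peak at bases 17026 to 19545 of the release 5 mitochondrial sequence. They stand out because nuclear protein binding was the object of the assay and the signal exceeds the caller's background there. No library's values are in the list, so no explanation was tested.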

How the results depend on the processing

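Of 44 alternative settings, 35 kept the direction and the side of the threshold, stayed within the interval of the value or, for a number of peaks, within 1.5 times of it, and 9 moved a value that had no test; none reversed a result. Keeping the top 50% of peaks by score left 3882 peaks, and the top 10% left 770, by construction; merging peaks within 1000 bp left 5733, and no peaks touched or overlapped. Uextra then held 52.1% and 43.1% of them, and 61.2% once peaks within 1000 bp were merged. The share rose on merging because more arm peaks were joined: 2625 arm peaks left 1592 regions, and 4114 Uextra peaks left 3510. The cause of the lower shares at higher score limits was not tested. The highest density over the arms, that of chromosome 4, was 5.27 times the lowest for the top 50% of peaks, and the ratio was 1.26 over the 5 large arms, by construction. Scores matched at the background rate of 80.06 made up 42.2% of arm peaks and 55.3% of Uextra peaks, and the rate itself did not change. Unmatched scores, above all high ones, can share that rate, so these are not the shares of all peaks at it. The cause of the difference was not tested. The share of arm peaks with a close neighbour was 58.7% at 2000 bp, 80.8% at 20000 bp and 47.9% for the top 50%, each above every random placement, and lay between 66.4 and 69.9% with each arm left out in turn; edge to edge, it was 40.6% and 18.9% with peaks within 1000 and 2000 bp merged, above every placement over the arms and within windows of 500 kb. The settings for runs, chromosome 4, proximal ends, Uextra, background rate, single arms and single classes, and merging for results other than the number of peaks, were chosen after seeing the data. No paired analysis was possible because the list holds no value per library; for the same reason, leaving out each replicate was not run, and neither were other settings for genomic features, start sites, gene lists and motifs, which need a release 5 annotation. Read depth is unknown, and its effect on the calls was not tested.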

Other observations

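The ends of some arms carried broad or regularly spaced enrichment. On 3L, the widest peak of the list spanned bases 40 to 19780 with a score of 48.32, and on 2L a 5234-bp peak spanned bases 29 to 5262 with a score of 63.87. These are the telomeric ends of those arms. At the far end of 3R, 6 peaks of 680 to 826 bp followed one another from bases 27898916, 27899918, 27900914, 27901996, 27902863 and 27903964, with scores between 47.23 and 64.65. The last peak of 2R, at bases 21145652 to 21146688, scored 51.92.

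The tests of merging, of density along the arms, of calls near the threshold and of the 2L block were chosen after the results they bear on were seen, and the bounds of the last were reworded after its p was known. The test of merging took its present form after earlier forms were seen, whose placements either allowed smaller gaps than merged peaks have or gave too many calls in simulated random lists. Those of run similarity and of Uextra copies were written down first.

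Weak peaks formed runs of 7 to 10 kb on 5 arms. Splitting of broad regions by the caller at gaps of up to 2000 bp is not the whole cause of the grouping of arm peaks. Regions merged across 2000 bp still had a close neighbour 2.50 times as often as under random placement. Splitting at wider gaps was not tested, so splitting as a whole is not excluded. Within runs, whose gaps are at most 2000 bp, splitting was not tested either. Broad differences in density along the arms are not the whole cause either, since the ratio was 2.57 for unmerged peaks against peaks moved by up to 250 kb. A candidate explanation for the 76 runs is copies of one repeated element, such as a transposable element: their peak positions overlapped by a median of 55.7% at the best orientation and shift, against 49.7 to 50.8% in 100 sets with the order of peaks and gaps shuffled within runs, a small excess. Whether any repeated element underlies the runs stays open, since no sequence or annotation was used, and no biological explanation was tested.

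Uextra held 53.5% of all peaks. Were these mainly calls near the threshold, its share of the top 10% should be under 26.8%. That share was 43.1%, between this bound and its share of the list, so the bound alone does not decide. Among peaks scoring 13.7 or more, Uextra still held 52.1%. Its lower quartile of scores was 11.055, against 10.87 on the arms. These values argue against calls near the threshold as the main source of its share. Its median (13.49 against 14.31) and upper quartile (17.62 against 28.32) were lower than on the arms, so a smaller part for such calls is not excluded. Near-identical copies were sought among the 1171 Uextra peaks at least 400 bp wide, as pairs with widths within 2 bp and scores within 1%. There were 200 pairs, 0.988 times the mean with scores reassigned among peaks of like width (range 173 to 237). This met the bound set beforehand, but the test cannot decide. Around the Uextra median score of 13.49, 1% is less than the step between neighbouring values at the background rate, such as 13.4 and 13.7. A difference of 1 fragment in pileup breaks a match there, so real copies could be missed. Copies whose peaks differ by more than these tolerances, narrower Uextra peaks, and copies of sequence outside Uextra were not tested. No biological explanation was tested, as the design holds no second condition.

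The 2L block at bases 21450215 to 21543676 had 12 peaks parted by 11 gaps of 55 to 1345 bp, with a best period of 4990 bp. A tandem repeat of the underlying sequence is a possible explanation, but neither test of the period passed the threshold. A first test, which shuffled the order of peaks and gaps, gave p = 0.295 (permutation, one-sided); it keeps the unit lengths and so says little, and it was replaced after that value was seen by gaps placed at random, which gave p = 0.0822 (permutation, one-sided). With 11 gaps, neither test of the period can tell a repeat apart from irregular gaps. Some successive peaks were of like width, which was not tested. Those from bases 21466240, 21471283 and 21476330 were 4672, 4606 and 4596 bp wide, and those from bases 21521245 and 21526093 were each 4328 bp wide. Over the whole block, widths ran from 2835 to 17987 bp. In the RefSeq gene table of release 6, 111 histone genes of 5 types neighbour one another on 2L with no other protein-coding gene between them; whether the block is that array was not tested, since no release 5 annotation was used.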
